A study of Homo sapiens with 8 samples.

How the data were processed

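Gene expression was measured by droplet single-cell RNA sequencing in 6 libraries of duodenal biopsies, 4 from patients with celiac disease and 2 from people with normal mucosa. Per the labels' protocols an epithelial fraction freed with a chelator and a reducing agent was combined with an enzyme digest of the rest before loading, and kits that read the 3′ and the 5′ end of transcripts were used, without saying which library used which. The deposited values are UMI counts per gene and barcode, made by the authors with Cell Ranger 7.1.0 against GRCh38, per the submitters' processing notes. A further 2 samples are antibody tag libraries of celiac 3 and celiac 4, and their tag counts stand as additional features in the deposited matrices of these libraries. The barcodes in every library outnumber the cells that the labels' protocol aimed to load. The feature tables list 36601 genes for healthy 1, healthy 2 and celiac 1 and 33538 genes for celiac 2, 3 and 4. Genes were matched by Ensembl identifier and printed by symbol, and positions come from a GRCh38 annotation. Of the 32732 shared genes 99 sex-linked ones were left out, which leaves 32633.

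Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5. Its automatic threshold marked under 0.5% of cells in 4 libraries, so in every library the cells with the highest scores were marked instead, at 0.8% per 1000 cells, and removed. This marked 307 and 242 cells of healthy 1 and 2 and 426, 1877, 2534 and 1607 of celiac 1 to 4. The 59284 cells left were clustered on 2500 variable genes and 40 principal components, with the libraries aligned by an own implementation of the Harmony algorithm, a graph of 20 nearest neighbours and the Leiden method (leidenalg 0.10.2) at resolution 0.7, which gave 51 clusters. A resolution of 1.0 had been planned and was changed after the clusters were seen. A cluster took a name from 202 fixed markers only where at least 3 markers were detected in 10% of its cells and its 10 leading genes, ranked by fold with a pseudocount of 10 CPM, did not contradict it. All other clusters stayed unnamed. Some list members are also naming markers, so that part of those lists also shaped the classes. Among them were 4 of the 21 brush border genes and 5 of the 23 lipid uptake genes for enterocytes. For crypt cells there were 5 of the 26 proliferation genes, and for plasma cells 6 of the 22 secretory genes. For macrophages there were 4 of the 12 resident macrophage genes.

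Cells are not replicates, so raw UMI counts were summed per library and class and the 4 celiac sums were compared with the 2 healthy ones. Libraries with under 20 cells of a class were left out of these tests. The main test was the quasi-likelihood test of edgeR 4.0.16 with TMM scaling and its standard filter on low counts, with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. DESeq2 1.42.0 was the other tool. Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a class, and again with an estimated correlation. A gene said to fall or rise when adjusted over the list alone was adjusted over the members of that list only. That adjustment does not cover the other lists or classes, and no gene passed the threshold over its class. Cell class and isotype shares were compared by two-sided exact permutation over the 15 splits of 6 libraries into 2 and 4, whose smallest p is 0.0667. The other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.

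Genes were to be named by a rule fixed before the data were examined. It takes those past the adjusted threshold, with a mean of at least 20 CPM in a group, all celiac libraries on one side of both healthy ones and the same sign with the annotation as a term, and fills up to 5 each way with the smallest unadjusted p where fewer pass. As no gene passed, all leading genes are such fillers. Other genes named are members of the fixed lists or were chosen for their known part in celiac disease, after their values were seen. Immunoglobulin and T cell receptor segments, HLA genes with common allele differences, sex-linked, mitochondrial and ribosomal protein genes were not eligible. Log2 differences are celiac over healthy from edgeR with their standard error. CPM given with an SD use TMM-scaled library sizes. Plain totals were used for DEFA5, for SPINK4 in macrophage-like cells, for tag-high against tag-low cells and for unnamed clusters.

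Each script that tests many genes was checked on simulated data with 200 genes changed in the real samples' means and spread. The changed genes were 67 at 2-fold, 67 at 4-fold and 66 at 8-fold. edgeR recovered 0%, 5.97% and 43.9% of them in enterocyte-like cells (15010 genes), 1.49%, 37.3% and 65.2% in crypt-like cells (14898 genes), 0%, 14.9% and 47.0% in T-like cells (14378 genes), 2.99%, 13.4% and 33.3% in plasma-like cells (14702 genes), 2.99%, 23.9% and 69.7% in macrophage-like cells (8859 genes) and 0% at each fold in whole libraries (21866 genes). DESeq2 recovered more, but 46 of its 138 calls in simulated enterocyte-like cells and 88 of its 155 in simulated whole libraries were false, so its counts are given only beside those of edgeR. Camera found a shifted set of 20 genes in each class, and at most 1 of 25 unshifted sets had an unadjusted p under 0.05. The simulated genes varied independently of each other. This check therefore cannot give the rate of false calls for real lists, whose members may vary together.

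Alternatives fixed in advance were DESeq2, library totals in place of TMM, no filter on low counts, the annotation as a term in the fit, the replicate number as a block, leaving out each library in turn, a mitochondrial limit of 10%, doublets kept, a minimum of 1000 UMIs, and other denominators for shares. Added after the data were seen were leaving out the cells high in the antibody tag in celiac 3 and celiac 4, a mitochondrial limit of 50%, adding unnamed clusters to the T-like and macrophage-like cells, and leaving out enterocyte-like clusters that come mostly from 1 library. Where leaving out a healthy library leaves 1, that lone library is assumed to vary like the celiac ones. Without celiac 1 every celiac library carries the smaller annotation and every healthy one the larger, so disease and annotation cannot be told apart there. No healthy library carries the smaller annotation. The annotation term leaves celiac 1 against healthy 1 and 2 as the difference, and celiac 2 to 4 add only to the estimated spread. Intervals and limits of a count of 0 cover counting error only.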

Results

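Droplet single-cell RNA sequencing was done on biopsies of the duodenum, the upper part of the small intestine, from patients with celiac disease, an immune disease of this tissue driven by gluten, and from people with normal mucosa. There were 4 celiac libraries (celiac 1 to 4) and 2 healthy ones (healthy 1 and 2), which the labels title separately and which are taken here as separate donors. The matrices held 20401 and 10918 barcodes with 95764834 and 73116079 UMIs (unique molecular identifiers, each standing for a counted RNA molecule) in healthy 1 and 2. They held 16250, 26208, 22212 and 17438 barcodes with 94204197, 117352970, 163477699 and 94539864 UMIs in celiac 1 to 4. The median UMI count per barcode was 1948 and 2766 in the healthy libraries and 2416, 1677, 3942 and 3140 in the celiac ones. The median share of mitochondrial UMIs, a sign of damaged cells, was 43.8% and 24.5% in the healthy libraries and 26.8%, 20.8%, 9.01% and 6.16% in celiac 1 to 4. Filters on depth, mitochondrial share and doublets left 5886 and 5256 healthy cells and 6874, 13439, 15265 and 12564 celiac cells. Healthy 1, healthy 2 and celiac 1 were counted against a table of 36601 genes and celiac 2, 3 and 4 against one of 33538. The annotation thus partly goes with the disease. A fit with the annotation as a term compares celiac 1 alone with healthy 1 and 2, so its changes may reflect that library.

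The cells fell into 51 clusters, and 42 of them were named from markers fixed before the data were examined. T-like cells (clusters 2, 3, 4, 15 and 50), plasma-like cells (1, 7, 23, 26 and 35), enterocyte-like cells, the absorptive cells of the villus (8, 12, 29, 39, 43 and 47), stem and transit-amplifying crypt-like cells (6, 11 and 21) and monocyte and macrophage-like cells (16 and 27) were numerous enough to be compared in all 6 libraries. Among the clusters left unnamed, cluster 0 was led by genes of naive T cells, among them LEF1, CCR7 and TCF7, although healthy 1, with 1118 cells in this cluster, held 63 CCR7 UMIs in the whole library, and cluster 13 by CCL4, ICOS, XCL1 and CD69, genes of activated lymphocytes. Cluster 18 was led by S100A8, S100A9, FCN1 and VCAN, genes of monocytes.

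Antibody tags, which label the cells of a suspension before loading, were counted in the matrices of celiac 3 and celiac 4. In each of these libraries the counts of the main tag formed a low and a high peak, with medians of 38 and 872 in celiac 3 and of 393 and 1698 in celiac 4. Cells above the emptiest bin between the peaks made up 55.7% of celiac 3 (8511 of 15265 cells, 95% Wilson interval 55.0% to 56.5%) and 65.7% of celiac 4 (8250 of 12564, 64.8% to 66.5%). In celiac 4 the peaks overlapped, with 13.1% of the cells near the parting value against 0.675% in celiac 3. B-like cells were 98.6% and 98.4% tag-high in celiac 3 and 4, cluster 0 was 99.4% and 98.9%, and cluster 18 was 94.5% and 89.8%. Plasma-like cells were 3.64% and 28.97% tag-high, crypt-like cells 3.38% and 23.2%, and macrophage-like cells 8.41% and 20.7%. Enterocyte-like cells were higher, at 12.5% and 45.5%, as were Brunner gland and mucous-like cells, another epithelial class, at 17.8% and 44.1%. T-like cells were divided, with 55.7% and 56.6% of them tag-high. Within the T-like cells, the summed level of CCR7 and LEF1, which guide and mark naive T cells, was 424 CPM (UMI counts scaled to a common library total) in tag-high against 22.4 in tag-low cells of celiac 3, and 410.5 against 16.2 in celiac 4. ITGAE, an integrin that holds lymphocytes in the epithelium, ran the other way, with 65.1 CPM in tag-high and 662 in tag-low cells of celiac 3 and with 117 and 597 in celiac 4. CXCR6, a receptor of tissue-resident T cells, was at 18.6 against 154 CPM in celiac 3 and at 43.6 against 194 in celiac 4. Values without the tag-high cells are given below for shares and list calls where they differ, but not for single genes in the class comparisons. Tags were counted in celiac 3 and celiac 4 alone. Leaving out tag-high cells thus takes nearly all B-like and cluster 0 cells from these libraries and none from the others. If staining follows the cell type, the shares left are shaped by this removal and by the smaller total.

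**Figure D1:**
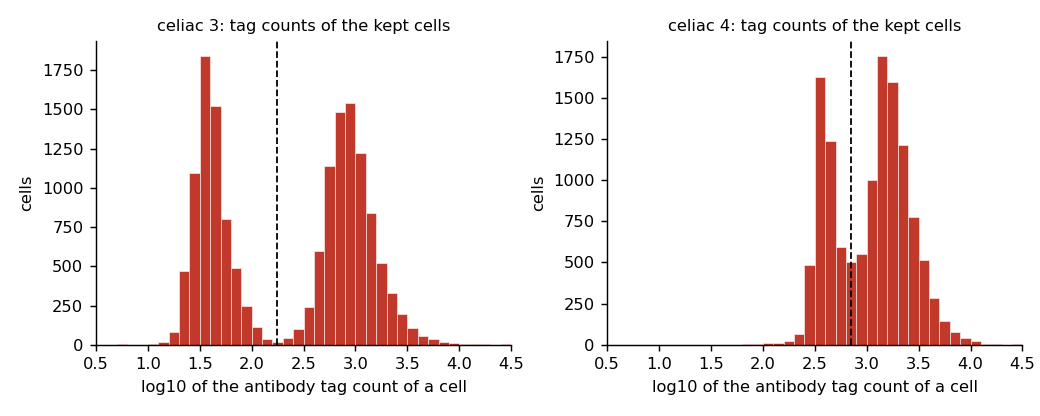
Number of cells (vertical axis) by log10 of the count of the main antibody tag (horizontal axis) in celiac 3 and celiac 4, with the parting value between the peaks at 177 and 707 counts. The tag-high cells make up 55.7% of celiac 3 and 65.7% of celiac 4.

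The first question was whether the cell make-up of the mucosa differed between disease and health. Paneth-like cells, which secrete antimicrobial peptides at the crypt base, were few but made up a larger share of every celiac library (14, 21, 22 and 22 cells) than of either healthy one (4 and 1 cells), with 0.170% against 0.0435% of all cells (exact p = 0.0667, adjusted p = 1.0). Without the tag-high cells they were at 0.270% in celiac (exact p = 0.133). Monocyte and macrophage-like cells were 2.24% of celiac and 3.05% of healthy cells and lower in 4 of 4 celiac libraries (exact p = 0.133), but without the tag-high cells the order turned, with 3.496% against 3.05%. B-like cells were 14.9% of celiac 3 and 6.08% of celiac 4, against 0.727% and 0.595% of celiac 1 and 2 and 2.16% and 0.723% of the healthy libraries. Without the tag-high cells, which were taken from celiac 3 and celiac 4 alone, the celiac mean of B-like cells was 0.522%. T-like cells made up 20.2% of celiac and 23.9% of healthy cells, and 22.0% of celiac cells without the tag-high ones. This share leaves out clusters 0, 13 and 28, which scored best as T cells but stayed unnamed. Cluster 0 alone made up 18.99% and 5.25% of healthy 1 and 2 and 5.18%, 6.21%, 19.5% and 32.0% of celiac 1 to 4. Without the tag-high cells it was at 0.252% and 1.02% in celiac 3 and 4. Plasma-like cells, which secrete antibody, were at 16.6% against 17.2% with all cells, but the difference was -23.63 percentage points with a mitochondrial limit of 10%. Among tag-low cells plasma-like cells reached 23.6% in celiac, with 26.8%, 15.1%, 29.8% and 22.6% in celiac 1 to 4, above both healthy libraries in 3 of 4 (exact p = 0.333). Enterocyte-like cells made up 17.97%, 8.02%, 2.52% and 4.81% of celiac 1 to 4 and on average 10.5% of the healthy libraries. Enteroendocrine-like cells, which release gut hormones, were 0.610% of celiac and 0.242% of healthy cells and higher in 3 of 4 (exact p = 0.2), with 0.111% in celiac 3. Among the epithelial cells of tag-low droplets they were 2.60% in celiac against 0.710% in healthy libraries and higher in 4 of 4 (exact p = 0.133). Cluster 13 made up 13.5% and 6.86% of the tag-low cells of celiac 3 and 4, against 0.131% and 0.0298% in celiac 1 and 2 and a healthy mean of 0.0931%.

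No class passed the threshold in the two-sided exact permutation test (19 classes, adjusted p = 1.0 for all), and none passed edgeR on cell numbers, where the lowest adjusted p was 0.565. With 2 against 4 libraries the smallest exact p is 0.0667, so this test cannot pass 0.05. Shares also moved with the mitochondrial filter, whose main limit was exceeded by 69.4% of the barcodes of healthy 1, the most of any library.

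**Figure D2:**
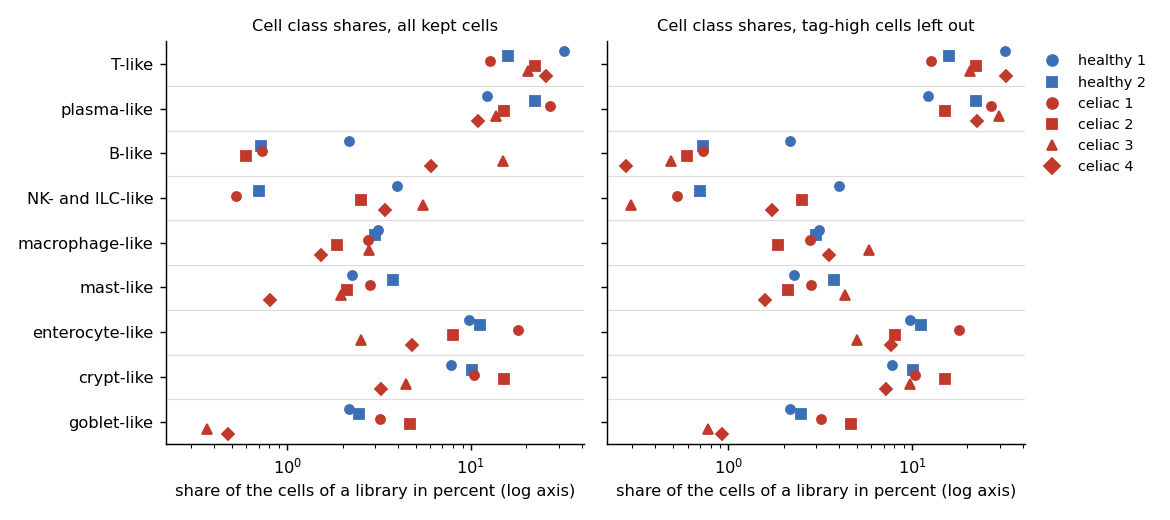
Share of 9 cell classes among the kept cells of each library, in percent on a log axis, with all cells (left panel) and without the tag-high cells (right panel). Each point is a library, and B-like cells stand at 14.9% in celiac 3 and 6.08% in celiac 4 on the left and at 2.16% or lower in the other libraries.

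The comparison of enterocyte-like cells asked what the absorptive epithelium expressed in disease. Genes of digestion and drug metabolism tended lower and genes of antigen presentation and cell division higher. CYP2C18, a cytochrome of xenobiotic metabolism, stood at 125 ± 34.8 CPM in celiac against 397 ± 69.0 in healthy libraries (SD, n = 4 and n = 2), a log2 difference of -1.67 (SE 0.32). TRMT11, a tRNA methyltransferase, and AGMO, an enzyme that cleaves ether lipids, were lower by a log2 difference of -1.58 and -1.62. RBM3, an RNA-binding protein induced by cold, was at 148 ± 34.9 against 45.3 ± 6.24 CPM (log2 difference 1.71, SE 0.33). ZYX, an actin-associated protein of focal adhesions, was at 35.5 ± 6.49 against 13.1 ± 2.30 CPM. HLA-DPB1, part of an MHC class II molecule that shows peptides to CD4 T cells, was at 90.2 ± 38.3 against 16.2 ± 5.41 CPM (log2 difference 2.47, SE 0.51).

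As a group, the 21 tested brush border genes of digestion and of sugar and peptide uptake were lower in celiac enterocyte-like cells, with 1 member above 0 and a median log2 difference of -0.60 (camera adjusted p = 1.83e-05, and adjusted p = 0.7003 with an estimated correlation). The peptide transporter SLC15A1 was at 259 ± 118 against 646 ± 183 CPM, and the protease MEP1B at 86.4 ± 28.1 against 195 ± 30.9 CPM. Sucrase-isomaltase (SI), also a marker behind the name of the class, was at 685 ± 199.9 against 1096 ± 124 CPM and lower in 4 of 4 celiac libraries. The xenobiotic and steroid metabolism list was lower in 15 of its 21 tested members (camera adjusted p = 0.00256, and adjusted p = 0.7003 with an estimated correlation), and 1 member, CYP2C18, fell when adjusted over the list alone. All 26 proliferation genes were higher, with a median log2 difference of 1.27 (camera adjusted p = 5.24e-06, and adjusted p = 0.7003 with an estimated correlation), among them the chromatin protein HMGB2 at 1.32 and the microtubule regulator STMN1 at 2.12. Of the 11 tested genes of MHC class II presentation 9 were higher, with a median of 0.90 (camera adjusted p = 0.0177, and adjusted p = 0.7003 with an estimated correlation), and HLA-DPA1 and HLA-DPB1 rose when adjusted over the list alone. This call ended with the annotation as a term (adjusted p = 0.783), with the replicate number as a block (0.260), without healthy 2 (0.2305) and without celiac 3 (0.0725). The 17 genes of MHC class I presentation were called higher (adjusted p = 0.0281, and adjusted p = 0.704 with an estimated correlation) but turned lower, with adjusted p = 0.218, when the annotation was a term in the fit. IL15, a cytokine that activates intraepithelial lymphocytes, did not stand apart, with 29.8 ± 9.02 against 33.3 ± 7.25 CPM. The transglutaminase TGM2, whose protein is the autoantigen of celiac disease, was at 20.1 ± 16.2 against 6.49 ± 1.54 CPM, with 2.73 CPM in celiac 1.

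Signs of RNA quality and of other cells moved with these groups. All 20 ribosomal protein genes were higher (median 0.87, adjusted p = 1.31e-12, and adjusted p = 0.7003 with an estimated correlation), as were all 20 genes of the dissociation and heat shock list (median 0.74, adjusted p = 0.000424, and adjusted p = 0.7003 with an estimated correlation). The plasma cell secretory list was higher as well (adjusted p = 0.00405, and adjusted p = 0.7003 with an estimated correlation) but turned lower without healthy 1 (adjusted p = 0.963). Higher too were the lists of inflammatory monocytes (adjusted p = 0.0177) and extracellular matrix (adjusted p = 0.0281), again with adjusted p = 0.7003 with an estimated correlation. The lipid uptake list was lower (adjusted p = 0.0281, and adjusted p = 0.7003 with an estimated correlation). The largest enterocyte-like cluster was 8 in healthy 1, celiac 2 and celiac 4 and 12 in healthy 2, celiac 1 and celiac 3, and clusters 29, 39, 43 and 47 came mostly from celiac 1 (327, 74, 48 and 34 of its cells).

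Over all 15010 genes tested in enterocyte-like cells 0 passed an adjusted p of 0.05 in edgeR, 1160 had an unadjusted p under 0.05, and DESeq2 called 39 (21 higher, 18 lower). The leading genes had an adjusted p of 0.622. Without celiac 1, where disease and annotation coincide, edgeR called 33, and without healthy 1 it called 2. The annotation as a term ended 5 of the 11 list calls (adjusted p from 0.114 to 0.783) and the replicate block 2 (0.0700 to 0.260). Leaving out healthy 1 ended 7 (0.237 to 0.963), healthy 2 ended 1 (0.231), celiac 1 ended 1 (0.197), celiac 2 ended 3 (0.142 to 0.182), celiac 3 ended 3 (0.0595 to 0.0968) and celiac 4 ended 1 (0.0657). Leaving out the tag-high cells ended 3 (0.09897 to 0.181), and the brush border, heat shock and ribosomal protein lists held in each of these fits.

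In the crypt-like cells, from which the epithelium renews itself, the comparison asked whether the progenitors differed. The leading genes included products of Paneth cells, which were higher, and an exchanger of the absorptive surface, which was lower. PLA2G2A, a bactericidal phospholipase made by Paneth cells (chromosome 1, 19975431 to 19980416, GRCh38), was at 48.5 ± 36.6 against 0.734 ± 0.884 CPM (SD, n = 4 and n = 2). PRSS2, a trypsinogen that Paneth cells store and whose sequence is close to that of other trypsinogens, so that reads may be shared (chromosome 7, 142760398 to 142774564), was at 90.0 ± 62.5 against 2.40 ± 0.441 CPM. SLC26A3, a chloride and bicarbonate exchanger of the absorptive surface (chromosome 7, 107765467 to 107803225), was at 164 ± 34.6 against 528 ± 87.8 CPM (log2 difference -1.69, SE 0.25). NCKAP5 was at 15.8 ± 2.02 against 41.8 ± 5.19 CPM, and the complement regulator CFI at 10.0 ± 2.61 against 27.2 ± 2.23 CPM. RBM3 was higher here too, at 230.1 ± 11.6 against 125 ± 24.4 CPM.

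All 21 tested brush border genes were lower in celiac crypt-like cells, with a median log2 difference of -0.83 (camera adjusted p = 1.47e-10, and adjusted p = 0.564 with an estimated correlation). MEP1B, at 4.44 ± 1.64 against 16.3 ± 1.14 CPM, fell when adjusted over the list alone, and the disaccharidase MGAM was at 5.05 ± 2.99 against 19.6 ± 8.81 CPM. The xenobiotic list was lower in 19 of 21 members (median -0.64, adjusted p = 1.16e-05, and adjusted p = 0.564 with an estimated correlation), with CYP3A4 at a log2 difference of -2.83. Lipid uptake and chylomicron assembly was lower in 20 of 23 (median -0.40, adjusted p = 0.000427, and adjusted p = 0.564 with an estimated correlation), with the lipoprotein APOB at -2.67. Iron, calcium and vitamin uptake was lower in 14 of 18 (adjusted p = 0.0061, and adjusted p = 0.564 with an estimated correlation), with the folate transporter SLC46A1 at 2.05 ± 1.65 against 9.27 ± 0.248 CPM. Proliferation genes were higher in 22 of 26 (median 0.38, adjusted p = 0.000533, and adjusted p = 0.564 with an estimated correlation), and turned lower without healthy 1 (adjusted p = 0.642). MHC class II presentation was higher in 10 of 11 (median 1.98, adjusted p = 0.00183, and adjusted p = 0.564 with an estimated correlation), with HLA-DMA, which loads peptides, at 68.3 ± 41.8 against 17.4 ± 0.391 CPM, but turned lower with the annotation as a term (adjusted p = 0.523). MHC class I presentation was called higher (adjusted p = 0.0351, and adjusted p = 0.648 with an estimated correlation) and was called lower with that term (adjusted p = 0.0172). Lymphocyte genes, which crypt cells should lack, were lower, with the NK receptor list down in 10 of 12 (adjusted p = 0.00183, and adjusted p = 0.564 with an estimated correlation). Its member CD160 fell when adjusted over the list alone, and the killer protease GZMA was at 6.81 against 50.9 CPM. The T cell activation list (adjusted p = 0.0255) and the resident macrophage list (adjusted p = 0.0377) were lower too, each with adjusted p = 0.564 with an estimated correlation.

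Paneth cell RNA was also higher in classes that should lack it. DEFA5, the most abundant Paneth cell peptide, was at 1603 against 17.0 CPM in crypt-like cells, at 117 against 13.5 in T-like cells and at 185 against 19.3 in macrophage-like cells. The heat shock list was higher in crypt-like cells (20 of 20, adjusted p = 0.00072, and adjusted p = 0.564 with an estimated correlation). Cluster 6 was the largest crypt-like cluster in all libraries but celiac 3, where cluster 11 was, and cluster 21 came mostly from celiac 2.

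Over 14898 genes in crypt-like cells edgeR called 0, with 569 at an unadjusted p under 0.05, and DESeq2 called 24 (13 higher, 11 lower). The adjusted p was 0.844 for NCKAP5 and SLC26A3 and 0.977 for the other leading genes. Without celiac 1 edgeR called 103, without healthy 1 it called 2 and without celiac 4 it called 1. The annotation as a term ended 7 of the 11 list calls (adjusted p from 0.0172 to 0.870) and the replicate block 4 (0.0597 to 0.608). Leaving out healthy 1 ended 9 (0.143 to 0.652), healthy 2 ended 1 (0.1198), celiac 1 ended 2 (0.0783 to 0.357), celiac 2 ended 1 (0.207), celiac 3 ended 1 (0.0835), celiac 4 ended 4 (0.0655 to 0.0886) and the tag-high cells 1 (0.134). The brush border call held in each of these fits, with adjusted p = 0.000523 without healthy 1.

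**Figure D3:**
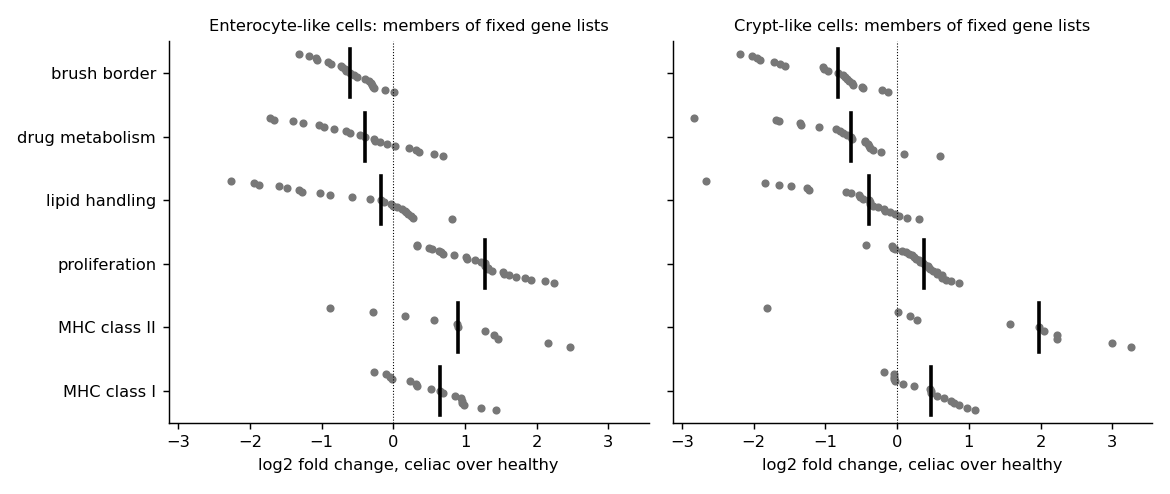
Log2 difference in expression, celiac over healthy, of the tested members of 6 gene lists in enterocyte-like and crypt-like cells, where each point is a gene and each bar the median of its list. The brush border genes have medians of -0.60 and -0.83, and the MHC class II genes 0.90 and 1.98.

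T-like cells were compared to see how mucosal T cells differ in disease. Interferon-stimulated antiviral genes were lower in celiac T-like cells than in the mean of the healthy libraries, and the healthy libraries lay far apart. IFIT3, an antiviral effector that interferon induces (chromosome 10, 89327894 to 89340971, GRCh38), was at 6.68 ± 1.45 CPM in celiac (SD, n = 4), against 12.4 in healthy 1 and 219.7 in healthy 2. RSAD2, which blocks viral replication, was at 8.22 ± 4.29 CPM in celiac against 15.1 and 249 in the healthy libraries. HLA-DPB1, which activated human T cells express, was at 100.1 ± 32.7 against 43.6 ± 6.90 CPM (log2 difference 1.20, SE 0.36). FOXP3, the master regulator of regulatory T cells, was at 20.0 ± 5.11 against 10.0 ± 4.32 CPM, above both healthy libraries in 4 of 4. IFNG, the interferon that gluten-specific T cells secrete, was at 184 ± 179.6 against 65.7 ± 66.6 CPM, and the killer protease GZMB at 329 against 139 CPM, with 783 in celiac 2, both within the spread of the libraries. These values include the tag-high cells, which were 55.7% and 56.6% of the T-like cells of celiac 3 and 4. In the tag-low T-like cells IFNG was at 345 CPM in celiac 3 and 93.4 in celiac 4, on plain totals.

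Of the 24 tested interferon response genes 20 were lower, with a median log2 difference of -0.91 (camera adjusted p = 5.12e-05, and adjusted p = 0.736 with an estimated correlation), and 8 fell when adjusted over the list alone, among them IFIT1, IFIT2, IFIT3 and MX1. Without healthy 2 the list was called neither way and pointed higher (adjusted p = 0.342). MHC class II presentation was higher in 9 of 11 members (median 0.71, adjusted p = 0.00856, and adjusted p = 0.736 with an estimated correlation), with the peptide loader HLA-DMA at a log2 difference of 1.24. Proliferation was higher in 21 of 24 (median 0.63, adjusted p = 0.0193, and adjusted p = 0.736 with an estimated correlation), with the cell cycle kinase CDK1 at 1.56 and STMN1 at 1.11, and it turned lower with the annotation as a term (adjusted p = 0.593). Genes of other cells moved as well. The plasma cell secretory list was higher in 19 of 22 (adjusted p = 1e-04, and adjusted p = 0.736 with an estimated correlation), and JCHAIN, the joining chain of secreted antibody, was at 786 ± 390.1 against 213 ± 59.4 CPM. SPINK4, a goblet cell product, was at 42.8 ± 16.8 against 10.3 CPM. Extracellular matrix genes were higher in 10 of 11 (adjusted p = 0.0311) and ribosomal protein genes in 20 of 20 (median 0.73, adjusted p = 5.76e-09), each with adjusted p = 0.736 with an estimated correlation.

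Over 14378 genes in T-like cells edgeR called 0, with 480 at an unadjusted p under 0.05, and DESeq2 called 33 (24 higher, 9 lower). The leading genes had an adjusted p of 0.922. Without the tag-high cells, which were 55.7% and 56.6% of the T-like cells of celiac 3 and 4, edgeR called 0 of 13608 with 398 at an unadjusted p under 0.05, and the interferon list kept its call (adjusted p = 0.000409). Without celiac 1 edgeR called 61 and without healthy 1 it called 2. The annotation as a term ended 3 of the 6 list calls (adjusted p from 0.360 to 0.593), MHC class II among them, and the replicate block 0. Leaving out healthy 1 ended 4 (0.153 to 0.958), healthy 2 ended 1 (0.342), celiac 1 ended 1 (0.0635), celiac 2 ended 2 (0.227 to 0.261), celiac 3 ended 1 (0.414) and the tag-high cells 1 (0.224). The largest T-like cluster was 4 in healthy 1 and celiac 1, 3 in healthy 2 and celiac 3, and 2 in celiac 2 and celiac 4.

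**Figure D4:**
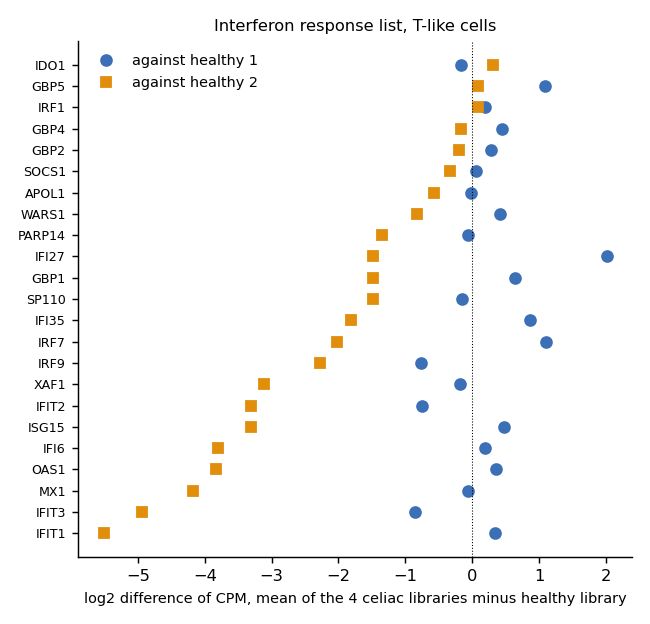
Log2 difference of the CPM of interferon response genes in T-like cells, mean of the 4 celiac libraries minus healthy 1 (circles) or healthy 2 (squares). Over the 24 tested members of the list the median is 0.23 against healthy 1 and -1.49 against healthy 2.

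Plasma-like cells were compared for the class of antibody they make and for their expression. IgM made up 26.2 ± 7.41% of heavy chain UMIs in celiac against 12.3 ± 2.43% in healthy libraries (SD, n = 4 and n = 2), with 23.5%, 22.9%, 37.2% and 21.1% in celiac 1 to 4 and 10.5% and 14.0% in healthy 1 and 2. IgA, the main secreted antibody of the gut, was lower, at 72.9 ± 7.75% against 87.2 ± 2.54%. All 4 celiac libraries lay outside the healthy range for both, at the smallest p that the two-sided exact permutation test allows (p = 0.0667, adjusted p = 0.1). IgG was 0.899 ± 0.435% against 0.557 ± 0.105% (exact p = 0.4). By the most abundant heavy chain per cell, IgM-producing cells were 19.9% in celiac against 6.96% in healthy libraries (exact p = 0.0667) and IgA-producing cells 78.1% against 91.2% (exact p = 0.2). FCRL2, a receptor of the Fc receptor-like family found on B lineage cells (chromosome 1, 157745733 to 157777132, GRCh38), was at 24.4 ± 4.19 against 10.3 ± 3.06 CPM, and SDF2L1, a protein of the endoplasmic reticulum that helps folding, at 299 ± 77.8 against 173 ± 1.41 CPM.

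**Figure D5:**
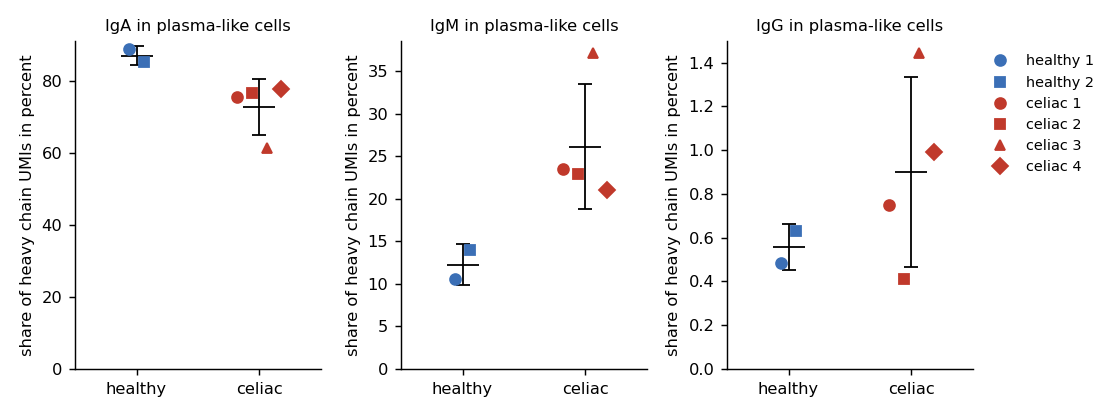
Share of heavy chain UMIs of plasma-like cells that come from IgA, IgM and IgG, in percent, where points are libraries and bars are the mean and SD of a group (n = 2 healthy, n = 4 celiac). IgM is at 21.1% or higher in the celiac libraries and at 14.0% or lower in the healthy ones.

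The secretory machinery of plasma cells was higher in 21 of 22 tested members (median 0.38, camera adjusted p = 2.84e-05, and adjusted p = 0.520 with an estimated correlation) and kept its call in each fit that left out a library. MHC class II presentation was higher in 9 of 11 (median 0.62, adjusted p = 0.00582, and adjusted p = 0.520 with an estimated correlation). Proliferation was higher in 20 of 22 (adjusted p = 0.00124), ribosomal protein in 18 of 20 (adjusted p = 0.00203) and heat shock in 18 of 20 (adjusted p = 0.003), and with an estimated correlation these had adjusted p = 0.7445, adjusted p = 0.7445 and adjusted p = 0.848. The heat shock list turned lower without healthy 1 (adjusted p = 0.584). Genes of other lymphocytes were higher in plasma-like cells too, with the cytotoxic list up in 19 of 19 (median 1.71, adjusted p = 0.000192, and adjusted p = 0.7445 with an estimated correlation). Its member GNLY, a pore-forming killer protein, was at 11.01 against 1.30 CPM, with 25.2 in celiac 4 and 6.58, 5.70 and 6.52 in celiac 1 to 3. The cytotoxic call ended with the annotation as a term (adjusted p = 0.147), with the replicate block (0.6295) and without celiac 4 (0.103). The list of CD4 helper and naive T cells was up in 9 of 10 (adjusted p = 0.0112, and adjusted p = 0.7445 with an estimated correlation), and lost its call without the tag-high cells (adjusted p = 0.268), without healthy 2 (0.1277), celiac 3 (0.371) or celiac 4 (0.4595). It turned lower with the annotation as a term (adjusted p = 0.889) and with the replicate block (0.6295). Of the interferon response genes 6 fell when adjusted over the list alone, among them MX1, IFI6 and the nuclear body protein SP110, while the list was not called (adjusted p = 0.291). Without healthy 2 MX1 and IFI6 turned to a log2 difference of 0.17 and 0.97.

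Over 14702 genes in plasma-like cells edgeR called 0, with 468 at an unadjusted p under 0.05, and DESeq2 called 12 (7 higher, 5 lower). The leading genes had an adjusted p of 0.912. Without celiac 1 edgeR called 44 and without healthy 1 it called 1. The annotation as a term ended 4 of the 7 list calls (adjusted p from 0.147 to 0.889), MHC class II among them, and the replicate block 3 (0.6295 each). Leaving out healthy 1 ended 2 (0.212 to 0.584), healthy 2 ended 2 (0.128 to 0.156), celiac 2 ended 1 (0.128), celiac 3 ended 1 (0.371) and celiac 4 ended 3 (0.103 to 0.459).

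In monocyte and macrophage-like cells the comparison asked about the inflammatory state of the mucosal myeloid cells. The class holds clusters 16 and 27, while cluster 18, led by S100A8 and S100A9, stayed unnamed and outside it. S100A8 and S100A9, alarm proteins of newly recruited monocytes, were at 19.5 ± 13.3 against 0.616 CPM and at 58.2 ± 34.3 against 5.36 ± 6.37 CPM (SD, n = 4 and n = 2). Celiac 1 lay apart from the other celiac libraries in both, at a log2 CPM of only 0.78 and 3.17. The neutrophil attractant CXCL8 was at 173 ± 133 against 30.9 CPM. CD40, the receptor by which T cells activate macrophages, was at 56.0 ± 15.1 against 16.7 ± 7.82 CPM (log2 difference 1.76, SE 0.43). C15orf48, a mitochondrial protein induced in inflammation, was at 26.7 ± 9.54 against 6.08 ± 0.122 CPM. GRAMD1B, which moves cholesterol from the plasma membrane, was at 28.8 ± 3.39 against 76.4 ± 5.22 CPM, and MVB12B, a part of the endosomal sorting machinery, at 72.0 ± 15.7 against 178 ± 6.60 CPM. CD163, a scavenger receptor of resident macrophages, was at 209.8 ± 67.2 against 254 ± 118 CPM.

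The inflammatory list was higher in 16 of 17 tested members (median 1.40, camera adjusted p = 0.00214, and adjusted p = 0.693 with an estimated correlation), and S100A8 and S100A9 rose when adjusted over the list alone. It lost its call without healthy 1 (adjusted p = 0.583), without celiac 4 (adjusted p = 0.0554) and with the replicate block (adjusted p = 0.679). Interferon response genes were lower in 18 of 26 (median -0.93, adjusted p = 0.0339, and adjusted p = 0.693 with an estimated correlation), and 7 fell when adjusted over the list alone, among them IFIT1 and IFI6, but without healthy 2 the list was called higher (adjusted p = 0.0188). This interferon call also ended without celiac 1 (camera adjusted p = 0.383), without celiac 3 (0.102) and without the tag-high cells (0.0702). The secretory list was higher in 22 of 22 (median 0.75, adjusted p = 5.84e-06), the epithelial antimicrobial list in 9 of 9 (adjusted p = 0.0129), proliferation in 15 of 16 (adjusted p = 0.018), ribosomal protein in 20 of 20 (adjusted p = 0.00234) and heat shock in 19 of 20 (adjusted p = 0.0129). Each of these 5 had adjusted p = 0.693 with an estimated correlation, and heat shock turned lower without healthy 1 (adjusted p = 0.818). The goblet cell product SPINK4 was also counted in this class, at 39.5 against 7.17 CPM, and how it came there was not tested.

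Over 8859 genes in macrophage-like cells edgeR called 0, with 518 at an unadjusted p under 0.05, and DESeq2 called 9 (3 higher, 6 lower). The leading genes had an adjusted p of 0.782. With no filter on low counts edgeR called 261 of 21098 (140 higher, 121 lower), without celiac 1 it called 37, and without healthy 1 it called 14. The replicate block ended 2 of the 7 list calls (adjusted p from 0.593 to 0.679). Leaving out healthy 1 ended 4 (0.0543 to 0.818), healthy 2 ended 3 (0.0188 to 0.642), celiac 1 ended 4 (0.0784 to 0.383), celiac 2 ended 1 (0.263), celiac 3 ended 1 (0.102), celiac 4 ended 3 (0.0554 to 0.2996) and the tag-high cells 1 (0.0702). This class held 157 to 428 cells per library, the fewest of the 5 compared except in celiac 3. There it held 428 cells against 385 enterocyte-like ones.

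Over all cells of a library, the hormone gene GIP, whose product enteroendocrine K cells release after meals (chromosome 17, 48958554 to 48968596, GRCh38), stood out, at 126 ± 104 CPM in celiac against 0.0615 ± 0.0145 in healthy libraries (SD, n = 4 and n = 2). TIMM10, which guides proteins into mitochondria, was at 48.1 ± 7.58 against 22.3 ± 3.06 CPM, and RBM3 at 156 ± 25.5 against 65.9 ± 14.2 CPM.

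All 21 brush border genes were lower over whole libraries (median -0.99, camera adjusted p = 1.91e-10, and adjusted p = 0.736 with an estimated correlation), although not called with the annotation as a term (adjusted p = 0.690). Xenobiotic metabolism was lower in 18 of 21 (median -0.98, adjusted p = 5.88e-07), lipid uptake in 19 of 23 (adjusted p = 1.41e-05) and iron, calcium and vitamin uptake in 13 of 18 (adjusted p = 0.00778), each with adjusted p = 0.736 with an estimated correlation, and these turned higher with the annotation as a term (adjusted p = 0.371, 0.0780 and 0.6002). The secretory list was higher in 21 of 22 (median 0.62, adjusted p = 2.41e-08), ribosomal protein in 20 of 20 (adjusted p = 2.08e-09) and heat shock in 20 of 20 (adjusted p = 0.000946), each with adjusted p = 0.736 with an estimated correlation. The inflammatory list was higher in 17 of 19 (adjusted p = 0.000146), MHC class II presentation in 9 of 11 (adjusted p = 0.0132) and resident macrophage genes lower in 11 of 12 (adjusted p = 0.000964), again with adjusted p = 0.736 with an estimated correlation. Cytotoxic genes were higher in 16 of 20 (median 1.05, adjusted p = 0.0172, and adjusted p = 0.868 with an estimated correlation), among them GNLY at 167 against 33.4 CPM. With the annotation as a term the cytotoxic list was called lower (adjusted p = 0.00638), and it turned lower with the replicate block (adjusted p = 0.267). Whole libraries also carry the tag-high cells and the differing share of each class, and without the tag-high cells the resident macrophage list had adjusted p = 0.324 and the iron uptake list adjusted p = 0.0922.

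Over 21866 genes in whole libraries edgeR called 0, with 379 at an unadjusted p under 0.05, and DESeq2 called 18 (16 higher, 2 lower). The leading genes had an adjusted p of 1. Without celiac 1 edgeR called 37. The annotation as a term ended 6 of the 11 list calls (adjusted p from 0.00638 to 0.887) and the replicate block 4, the inflammatory and MHC class II calls among them (0.2205 to 0.429). Leaving out healthy 1 ended 5 (0.111 to 0.944), healthy 2 ended the MHC class II (0.490) and cytotoxic calls (0.0639), celiac 2 ended the resident macrophage call (0.0692), celiac 3 ended the iron uptake (0.253), MHC class II (0.123) and cytotoxic calls (0.253), and celiac 4 ended the cytotoxic call (0.620).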

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

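The tests of a second suspension, of tag staining by cell type, of fewer epithelial cells, of the annotation, of a 5′ kit and both tests of the interferon pattern were chosen after the result was seen.

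The antibody tags of celiac 3 and celiac 4 were used in no planned comparison, 55.75% and 65.66% of their kept cells were tag-high, and B-like cells and naive lymphocyte genes were high in these libraries alone. Tag-high T-like cells carried at least 18.93 times the CCR7 and LEF1 level of the tag-low ones in both libraries, which a second cell suspension, tagged and mixed with untagged biopsy cells, would give. Fewer epithelial cells would raise all immune classes alike, but B-like to plasma-like cells stood at 0.5559 or higher against at most 0.178 elsewhere. A second suspension and staining that follows the cell type cannot be told apart, because the T-like cells part largely by cluster, with cluster 2 at 2.656% and 15.45%, cluster 3 at 77.03% and 93.04% and cluster 15 at 10.38% and 50.21% tag-high in celiac 3 and 4. The parting was also less sharp for epithelial cells of celiac 4, with 45.53% of enterocyte-like cells tag-high against 12.47% in celiac 3. A second suspension may be a source of the B-like and naive lymphocyte cells, and its origin is not given in the sources used here. A difference between patients stays open as untested.

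Interferon response genes were lower in celiac T-like and macrophage-like cells. Without healthy 2 the list in T-like cells pointed higher with adjusted p = 0.342 (from 7.05e-24 to 0.736 over the alternatives run). Against healthy 1 alone the members had a median log2 difference of 0.2316, with quartiles of -0.0874 and 0.457 and 15 of 24 members above 0, while against healthy 2 the median was -1.49. These values argue against a level of the list as a group below that of each healthy donor, though members such as IFIT3 and RSAD2 lay below both, at 6.68 against 12.4 and 219.7 CPM and at 8.22 against 15.1 and 249 CPM. An interferon response in 1 healthy donor may account for the call in T-like cells, and its cause was not tested. In macrophage-like cells the call also ended without celiac 1, without celiac 3 and without the tag-high cells.

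In 4 genes, FKBP2, ENAM, CHTF8 and CHD1L, celiac 1 lay near the healthy libraries and celiac 2, 3 and 4 far above, and of 9467 genes these 4 and PTP4A1 had celiac 1 within 2 times the healthy mean and the others at least 8 times above it. FKBP2 in celiac 1 was apart from the other celiac libraries at a log2 CPM of 3.44 in crypt-like cells, 4.7 in plasma-like cells and 4.18 over the whole library, ENAM was at -0.13 in plasma-like cells and CHD1L at 1.61 in crypt-like cells. Leaving these 4 out, 9 of 11342 genes were at least 4-fold higher in celiac 2, 3 and 4 than in the other libraries, as these genes are, and 50 lower, against at most 8 one way in the 9 other splits of the libraries 3 against 3. Of the 4 genes, 4 were above 2 times the healthy mean in both celiac 2 and celiac 3. They were picked for being high there, so this outcome was fixed and cannot decide on a 5′ kit in 1 library alone. Such a library could be celiac 4, whose barcodes start unlike those of the others. Counting against different annotations may set these genes but cannot be told apart from another difference between the same libraries, since so few genes go this way, and a kit shared by celiac 2, 3 and 4 or a difference between patients was not tested.

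A further 18 values lay apart from the other celiac libraries by Dixon's gap criterion for 4 samples. It was met 23 times in 197 values looked at, where chance gives about 1 in 20 groups. Erythroid-like cells were 2.149% of celiac 4. Fibroblast-like cells were 7.679% of celiac 2. Tuft-like cells, chemosensory epithelial cells, were 1.222% of celiac 1. In plasma-like cells of celiac 3 IgA was at 61.39% and IgM at 37.16%. In log2 CPM, enterocyte-like cells of celiac 2 had MEP1B at 5.51 and the fatty acid receptor CD36 at 5.5. Crypt-like cells had MEP1B at 1.34 in celiac 2. In celiac 1 crypt-like cells had HLA-F at 5.1, the sterol exporter ABCG8 at 3.0 and the cyclin CCNA2 at 4.7. T-like cells had GFOD1 at 5.39 in celiac 1. Plasma-like cells had FCRL2 at 4.23 in celiac 2 and GNLY at 4.69 in celiac 4. Macrophage-like cells of celiac 1 had S100A8 at 0.78 and S100A9 at 3.17. Over whole libraries the heme exporter FLVCR1 was at 4.3 in celiac 1 and the sulfotransferase SULT1E1 at 2.16 in celiac 3.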

How the results depend on the processing

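Leaving out tag-high cells, a mitochondrial limit of 50% and changes of the clusters in a class were chosen after the data were seen. Of 176 genes tested singly, 141 kept their direction under every alternative run or changed sign in a move within their standard error. Genes named below as turned moved by more than that error. Direction was also kept in every alternative by 38 of the 53 called lists and 7 of the 21 shares of cells and antibody classes. The leading genes kept theirs too. The rule picked them for lying wholly above or below both healthy libraries and for the same sign with the annotation as a term. Their outcome was therefore largely fixed in advance, and they are among the 176 genes. The cause was not tested for any result below unless stated. With the mitochondrial limit of 10% healthy 1 kept 9 enterocyte-like cells and was left out, and that fit of healthy 2 against the 4 celiac libraries called 1 gene and turned ABCB1 (0.63), MCM7 (-0.08), COL4A2 (-0.04), APOA4 (1.54), CYP3A4 (0.34) and REG1A (-0.06) in log2 difference. Library totals in place of TMM moved the median log2 difference of all genes from -0.0187 to -0.265 in plasma-like cells, from -0.00561 to -0.144 in macrophage-like cells and from 0.0878 to -0.146 over whole libraries. Depth limited the macrophage-like cells, where the filter left 8859 genes.

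Against 0 genes in edgeR, DESeq2 called 39 in enterocyte-like, 24 in crypt-like, 33 in T-like, 12 in plasma-like and 9 in macrophage-like cells and 18 over whole libraries, and macrophage-like cells had 261 with no filter. Leaving out each library gave 0 to 33, 0 to 103, 0 to 61, 0 to 44, 0 to 37 and 0 to 37, the highest without celiac 1, where disease and annotation coincide. Of 53 list calls 0 held with an estimated correlation, and leaving out a library gave 36 to 81 calls.

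The replicate block compared the pairs numbered 1 and 2. Different donors share only a number, and their deviations correlated at 0.0521 and 0.217. With the block 2 genes passed over whole libraries and 57 lists were called, 38 of them among the 53. It turned the CD4 T cell list in plasma-like cells (adjusted p = 0.6295) and the cytotoxic list over whole libraries (0.2668), and it turned LCT in enterocyte-like cells (-1.85), EGR1 in crypt-like cells (-0.09), ZFP36 (-0.12), IDO1 (-0.30) and IL1B (-0.22) in macrophage-like cells and ZFP36 over whole libraries (-0.03).

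With the annotation as a term these lists turned, in adjusted p: MHC class I in enterocyte-like (0.2182) and crypt-like cells (0.01716), MHC class II in crypt-like (0.523), proliferation in T-like (0.5932) and the CD4 list in plasma-like cells (0.889), and over whole libraries the cytotoxic (0.006382), iron (0.6002), lipid (0.07797) and xenobiotic lists (0.3712). As this term leaves only celiac 1 to compare with healthy 1 and 2, an annotation effect and a trait of celiac 1 cannot be told apart here. In log2 difference the annotation term turned PSMB9 (-0.18), TGM2 (-1.24), CXCL10 (-2.44), GBP5 (-0.49) and DUOX2 (-2.32) in enterocyte-like cells, HLA-F (-0.62), CCNA2 (-0.15), EGR1 (-0.36) and MKI67 (-0.14) in crypt-like cells, IL21 (-5.24) and GZMB (-0.01) in T-like cells, CXCL9 (-0.92), GBP5 (-1.26) and IDO1 (-2.06) in macrophage-like cells and S100A9 over whole libraries (-0.91).

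Leaving out single libraries gave these ranges of adjusted p for lists that turned: secretory in enterocyte-like cells 1.201e-06 to 0.9634, proliferation in crypt-like cells 2.473e-09 to 0.6419, interferon in T-like cells 7.053e-24 to 0.342 and in macrophage-like cells 1.247e-17 to 0.3828, with 0.01882 without healthy 2, and heat shock in plasma-like cells 3.616e-08 to 0.584 and in macrophage-like cells 4.263e-07 to 0.8184. It gave log2 differences of -1.68 to 0.34 for APOA4, -2.06 to 0.00 for CYP3A4 and -1.24 to 0.73 for LCT in enterocyte-like cells, -6.56 to 0.62 for IFI6 in crypt-like cells, -5.71 to 0.37 for IFIT1 in T-like cells, -4.21 to 0.17 for MX1 and -5.41 to 0.97 for IFI6 in plasma-like cells, and -5.05 to 0.14 for IFIT1, -1.43 to 2.95 for CXCL10 and -0.69 to 0.30 for CD163 in macrophage-like cells. IL15 turned to 0.22 in enterocyte-like cells with a limit of 50%. Adding unnamed clusters turned IL21 (-0.06) and CD8A (-0.20) in T-like cells and IL15 (0.31) in macrophage-like cells.

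Shares in percentage points, celiac minus healthy, turned by more than the spread between libraries in the comparison of celiac 1 with the healthy libraries alone for NK (-1.816), enterocyte-like (7.477), plasma-like (9.594) and tuft-like cells (0.605), among epithelial cells for crypt-like (7.255) and tuft-like cells (0.4226), and without tag-high cells for macrophage-like cells (0.4475). Leaving out the tag-high cells also turned, by less than that spread, plasma-like (6.37), crypt-like (1.663), NK (-1.075), B-like (-0.918), tuft-like (0.1255), goblet-like (0.07155) and endothelial-like cells (0.01841). Shares that moved by more than the spread without turning were those of plasma-like (-23.63), macrophage-like (-2.79) and Paneth-like cells (0.2887) with a limit of 10%, macrophage-like cells with a limit of 50% (-2.194) and among immune cells (-1.512), Paneth-like cells without the tag-high cells (0.2264), and Paneth-like (0.9003), enteroendocrine-like (1.862) and BEST4-like cells (-1.157) among epithelial cells.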

Other observations

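The genes described here, the cell groups compared and their tests were all chosen after the data were seen.

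Cells filled with GIP RNA were found among enteroendocrine-like cells of every celiac library. Of 268 celiac cells of this class 30 held at least 10 GIP UMIs (11.2%, 95% Wilson interval 7.95% to 15.5%), with 4 of 61, 14 of 136, 2 of 17 and 10 of 54 in celiac 1 to 4. Among the healthy cells it was 0 of 26, and the 95% Wilson interval allows a share of up to 12.9%, so these few cells leave open whether the shares differ. The class summed to 1 and 0 GIP UMIs in the healthy libraries and to 7251, 8539, 515 and 14083 in celiac 1 to 4, with only 5 and 21 healthy cells against 61, 136, 17 and 54 celiac ones. GIP is also a marker behind the name of this class.

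Cluster 13 came mostly from celiac 3 (70.9% of its 1302 cells). Among tag-low cells of celiac 3 and celiac 4 it carried more of the NK cell adhesion molecule NCAM1 than T-like cells (85.5 against 13.02 CPM, and 99.1 against 6.64) and more GZMK (316 against 67.1, and 276 against 29.1). The immediate early gene FOS, which rises with dissociation, was at 2383 against 699 and 4809 against 1280 CPM. CD3D, part of the T cell receptor complex, was lower (594 against 993, and 642 against 1148), as was ITGAE (148 against 662, and 116 against 597). The T cell marker CD3E lay nearer to the T-like cells, at 372 against 409 and 893 against 1121 CPM. By its markers the cluster scored 1.8 for T cell and 1.584 for NK cell and innate lymphoid cell, so these genes do not settle its type.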
